A study of Mus musculus with 9 samples.

How the data were processed

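Gene expression was measured in liver lobes of male C57BL/6 mice aged 3 months on 9 single-colour Agilent mouse arrays, with 3 arrays for each of 3 groups: untreated, treated with an adeno-associated virus (AAV) carrying green fluorescent protein (AAV-GFP), and treated with an AAV carrying the human glucocorticoid receptor β isoform (AAV-hGRβ). Per the labels' protocols, total RNA was purified on silica columns with a DNase step, and Cy3-labelled complementary RNA was made from 500 ng of it. Groups and replicate numbers were taken from the sample labels. The labels do not say that the replicates are separate animals, so every p-value measures the spread between these samples, which can be technical.

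Per the file headers, each array file held the spot intensity on a linear scale in a single Cy3 channel, with background and spatial trend removed within the array by the scanner software and with no scaling between arrays. The software was Agilent Feature Extraction 9.5, per the submitters' processing notes. Other columns held mean and local background intensity, and flags for spots well above background, saturated or non-uniform, also per the file headers. The deposited series table held the same processed intensity values, linear and not centred, with a largest absolute difference of 0 from the array files over all spots, and its column medians ran from 34.2 to 75.6. No step after the scanner software was given in the sources used here.

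Each array held 45018 spots, of which 43379 were gene spots for 41174 probes. Control spots and spots marked as outliers by the software were left out, and spots of the same probe were averaged. The values were log2 of the processed intensity minus the array's own 75th percentile, so that a value of 0 lies at that percentile. A probe was kept if it was well above background on all arrays of at least 1 group, which left 24288 probes. The probe with the highest mean stood for a gene with several probes (5479 genes), and 16801 genes were tested. Probes were named through a table of RefSeq names for assembly GRCm38.p6, used for names only: 22951 by accession, 6659 by symbol, 3109 by older symbol and 294 by gene identifier, while 8161 kept the name in the files. Probe positions are those of the array files, on build mm7. Saturation was recorded for 3 spots over the 9 arrays.

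Signal over background sets what the arrays could measure. Between 54.0% (untreated replicate 3) and 82.0% (AAV-hGRβ replicate 1) of gene spots were well above background, and the median processed intensity per array lay between 37.7 and 79.0. With 3 arrays per group, the number of arrays limits the precision. Where all probes of a gene were not well above background on any array of a group, the difference is given as "at least N-fold": the mean of the brighter group against the mean of a floor that is, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal of any probe well above background.

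Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, over all 9 arrays with 6 residual degrees of freedom), followed by Benjamini-Hochberg adjustment within each of the 3 comparisons at 0.05. Every adjusted p of a gene comes from limma. Gene lists (44 in all: pathways, hormone targets, liver zones and markers of cell types) were written before the data were examined, as were the groups, the main tests, most of the alternatives and the rule for naming genes. Of 1166 list entries, 1142 were on the array and 1075 were tested. Lists with at least 5 tested genes were compared with all other genes by limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, a rotation test of whether the genes of a list move, on balance, in a single direction. Each list also has a count of genes adjusted over the list alone.

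The rule for named genes took 10 genes of interest in each comparison, and, from genes past the threshold whose groups do not overlap, the 12 largest rises and the 12 largest falls for AAV-hGRβ against AAV-GFP and 8 of each for the other comparisons. It also took up to 4 members with the smallest p of each list that changed and up to 3 of each other list. Where fewer than 10 genes passed, the 10 with the smallest p were taken and are said not to have passed. Of the genes that this rule took, 2 are not reported here, 1 of them a gene of interest. Names that are only identifiers were counted but passed over in the ranking by size.

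The files give slide and scan day. The arrays lay on 5 slides and were scanned on 2 days, with 6 arrays on day 1 and 3 on day 2. Each day holds all groups, so scan day was fitted as a block and differences were also taken within each day. A slide held a single group except for the slide with AAV-GFP replicate 3 and AAV-hGRβ replicate 1, so slide was fitted as a random block, and as a fixed block where possible.

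Alternatives were normexp background correction with an offset of 50, the same after local backgrounds over 2 times the array median were replaced by that median, quantile normalization, scaling to the median, the deposited series table, no filter on dim probes, a filter asking for signal on all arrays, the mean of a gene's probes, only the groups compared, eBayes with trend and robust settings, a minimum change of 1.5-fold, blocks for slide, scan day and replicate number, and leaving out each array in turn. Simulated data held the real means and spread of 16801 genes, with arrays drawn independently and no shared signal of slide or scan day. They were used to test the gene model, which may make more false calls on the real arrays. For AAV-hGRβ against AAV-GFP it recovered 38% of genes changed by 1 on the log2 scale and 73% of those changed by 2, with 7 false calls. For AAV-hGRβ against untreated it recovered 35% and 71%, with 9 false calls, and for AAV-GFP against untreated, where none was changed, it made 0 calls. Figures were drawn with matplotlib 3.10.9, and files were read with pandas 2.3.3 in Python 3.11.15.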

Results

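Liver RNA of 3-month-old male C57BL/6 mice was profiled on 9 arrays: 3 from untreated mice, 3 from mice given AAV-GFP and 3 from mice given AAV-hGRβ. AAV is a small virus used to carry a gene into tissues such as liver, and AAV-GFP is the control for the vector. The β isoform of the human glucocorticoid receptor is a splice form with a different carboxyl end from the hormone-binding α isoform. The study asks what this isoform does in mouse liver. Values below are log2 signal relative to the 75th percentile of the same array, as mean ± SD with n = 3 arrays per group. Between 54.0% and 82.0% of gene spots were well above background on an array. Over 16801 genes, arrays of the same group correlated at 0.973 to 0.988 and arrays of different groups at 0.950 to 0.989.

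Genes of the interferon response rose in AAV-hGRβ compared with AAV-GFP livers, and their list had the largest median rise of the lists tested. Cell cycle genes (median 1.34) and T and NK cell markers (1.31) came next, and the difference between these lists was not tested. Ifi44, an interferon-induced antiviral gene, stood at 4.02 ± 0.56 with AAV-hGRβ and at -0.22 ± 0.49 with AAV-GFP, a log2 difference of 4.24 (SE 0.35, adjusted p = 0.00305), while its other probe gave 2.13. Irf7, a transcription factor that drives type I interferon production, rose from 0.86 ± 0.36 to 3.51 ± 0.28 (adjusted p = 0.00305). Ifnb1, which encodes interferon β, was not well above background on any AAV-GFP array and was at least 5.12-fold higher with AAV-hGRβ, with the smallest adjusted p of the comparison (0.000663). Members of the 2′-5′ oligoadenylate synthetase family, which senses double-stranded RNA, rose as well: Oas1f by 3.31, Oas1a by 3.25 and Oasl2 by 3.56, while Oas1b was at least 1.83-fold higher. Of 45 interferon-stimulated genes tested, 24 rose and 0 fell over all genes tested, and 41 rose when adjusted over the list alone. The median log2 difference of that list was 1.53 (camera adjusted p = 1.23e-48, and adjusted p = 0.0492 with an estimated correlation), with 1.57 on scan day 1 and 1.5 on scan day 2. With scan day as a block the list had adjusted p = 5.29e-41, and adjusted p = 0.0905 with an estimated correlation. Sensors of foreign DNA and RNA gave 3 of 19 higher, or 8 adjusted over the list alone (adjusted p = 3.38e-07, and adjusted p = 0.0489 with an estimated correlation). Among them, Zbp1, a sensor of Z-form nucleic acid, rose by 2.50 and Dhx58, a regulator of RIG-I-like receptors, by 1.72. The 3 sensors that passed (these and Irf7) are also in the interferon list, and 5 of the 19 sensors are in another list, so the 2 lists are not separate results. For the sensors the medians were 0.42 over all arrays, 0.40 on day 1 and 0.58 on day 2, and adjusted p = 0.0805 with an estimated correlation and scan day as a block.

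Markers of immune cells rose in the same livers. Cd8a, a coreceptor of cytotoxic T cells, was at -1.14 ± 1.04 with AAV-hGRβ, was not well above background on any AAV-GFP array, and was at least 12.7-fold higher (adjusted p = 0.00855), while its other probes gave log2 differences of 2.68 and 3.17. Gzma and Gzmb, granzymes of cytotoxic lymphocytes, rose by 3.73 and 2.35. T and NK cell markers gave 5 of 28 higher, or 19 higher and 1 lower adjusted over the list alone. Their median was 1.31, with within-day medians of 1.48 and 0.94 (adjusted p = 6.85e-12, and adjusted p = 0.113 with an estimated correlation). Ly6d, a surface protein of lymphoid precursors, rose by 4.18 and Bst2, an antiviral membrane tether, by 1.24. They were the 2 of 13 dendritic cell markers that rose, against 4 adjusted over the list alone, with a median of 1.11 (adjusted p = 9.59e-07, and adjusted p = 0.113 with an estimated correlation). Neutrophil and monocyte markers had 1 of 16 higher, Ly6c1 with 2.85, and 4 adjusted over the list alone. The median was 1.07 (adjusted p = 4.02e-06, and adjusted p = 0.212 with an estimated correlation). Kupffer cell and macrophage markers had 1 of 20 higher, the perforin-like gene Mpeg1 with 1.56, and 3 adjusted over the list alone. Here the median was 0.61 (adjusted p = 3.51e-07, and adjusted p = 0.248 with an estimated correlation). Within days the medians of these last 3 lists were 1.33 and 0.44, 1.5 and 0.29, and 0.91 and 0.33. B and plasma cell markers, with 0 of 13 passing over all genes and 1 adjusted over the list alone, had a median of 0.64, although the list turned direction under normexp correction, unless bright local backgrounds were replaced. They had adjusted p = 0.00299, and adjusted p = 0.248 with an estimated correlation, and medians of 0.80 on day 1 and 0.30 on day 2. Gzmb (adjusted p = 0.14) and Bst2 (adjusted p = 0.105) did not pass with slide as a random block.

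Chemokine, stress and cell division genes rose beside them. Ccl4 and Ccl5, chemokines that draw T cells, rose by 3.22 and 2.97, and Tnf and Traf1, of tumour necrosis factor signalling, by 1.54 and 1.58. The list of inflammatory cytokines and NF-κB targets had 6 of 31 higher and 12 adjusted over the list alone. Its medians were 0.74 over all arrays, 1.29 on day 1 and 0.24 on day 2 (adjusted p = 1.09e-08, and adjusted p = 0.166 with an estimated correlation). Among p53 targets, Phlda3, an inhibitor of AKT signalling, rose from 0.40 ± 0.13 to 3.11 ± 0.63 (adjusted p = 0.00647). Psrc1 rose by 3.26, Eda2r by 2.88 and Cdkn1a, the p21 inhibitor of cell division, by 2.40. The p53 list had 6 of 24 higher and 12 adjusted over the list alone. Its median was 0.87, with within-day medians of 1.02 and 0.68 (adjusted p = 1.04e-11, and adjusted p = 0.113 with an estimated correlation). Cell cycle genes had 7 of 38 higher and 30 adjusted over the list alone. The median of these was 1.34, with within-day medians of 1.45 and 1.44 (adjusted p = 1.55e-22, and adjusted p = 0.113 with an estimated correlation). They included the proliferation marker Mki67 (2.06), the spindle protein Prc1 (1.77), the mitotic checkpoint kinase Bub1b (1.34) and cyclin B1, Ccnb1 (1.23). Probes of Ccnb1 ranged from 1.23 to 3.11 and those of Psrc1 from 1.94 to 3.26. Targets of NRF2, the regulator of the oxidative stress response, had 5 of 30 higher and 6 adjusted over the list alone. Their median stood at 0.43, and at 0.36 and 0.31 within days (adjusted p = 1.13e-06, and adjusted p = 0.163 with an estimated correlation). Cbr3, a carbonyl reductase, rose most of these, from 0.39 ± 0.43 to 4.53 ± 0.79 (adjusted p = 0.00409), followed by the glutathione transferases Gsta2 (2.38) and Gsta1 (1.66), the quinone reductase Nqo1 (1.5) and sulfiredoxin, Srxn1 (1.49). Antigen presentation genes had 0 of 19 passing over all genes and 5 adjusted over the list alone. That list's median was 0.42, with within-day medians of 0.26 and 0.68 (adjusted p = 1.76e-05, and adjusted p = 0.166 with an estimated correlation). With slide as a random block Ccl4, Phlda3, Psrc1, Bub1b, Cbr3, Gsta2 and Srxn1 passed, and the other genes named in this paragraph did not (adjusted p from 0.0545 for Gsta1 to 0.134 for Mki67).

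Other genes with large rises were Ly6a (3.99), a surface marker induced by interferon, and Slfn4, a Schlafen family gene that was at least 6.02-fold higher. Wfikkn2, a secreted protease inhibitor, passed (adjusted p = 0.0223) on a probe not well above background on any AAV-GFP array, and stood at -0.28 under normexp correction. Without the filter on dim probes another probe, which the filter had removed, stood for the gene at -0.0236. Atf3, a stress-induced transcription factor, rose by 1.84 (adjusted p = 0.0892 with slide as a random block), although its list of unfolded protein and integrated stress response genes did not pass (1 of 31 higher, adjusted p = 0.449). The list of drug metabolism genes, which also holds Gsta1 and Gsta2, had 2 of 37 higher and did not pass (adjusted p = 0.876). Falls were fewer. Gas1, a growth arrest protein, fell from 0.70 ± 0.25 to -0.96 ± 0.39 (adjusted p = 0.0235). Polr3g, a subunit of RNA polymerase III, fell by 1.44. Fras1, an extracellular matrix protein, was at least 1.90-fold lower and not well above background on any AAV-hGRβ array. Icam4 fell by 1.39, Camk2n2 by 1.36, Carmil1 by 1.26, Spsb4 by 1.26, the cochaperone Bag2 by 0.97, Fam222a by 0.87 and the retinol saturase Retsat by 0.86. With slide as a random block Polr3g and Fras1 passed, and the other 8 of these falls did not (adjusted p from 0.0871 for Bag2 to 0.178 for Camk2n2). Probes of Polr3g ranged from -1.44 to -0.48 and those of Carmil1 from -1.26 to -0.63. On build mm7 the probe of Ifi44 lies on chromosome 3 from 151631285 to 151631344 and that of Ifnb1 on chromosome 4 from 87925845 to 87925904. The probe of Cbr3 lies on chromosome 16 from 93751054 to 93751113 and that of Gas1 on chromosome 13 from 59283463 to 59283522.

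Metabolic lists were lower by small amounts in AAV-hGRβ compared with AAV-GFP, and 16 of the 18 lower lists turned direction under normexp correction. With bright local backgrounds replaced before that correction, 0 lists turned and 17 of the 18 kept their call. The list of ribosomal proteins also turned under quantile normalization, without AAV-GFP replicate 3 and on scan day 1 alone. Amino acid and urea metabolism had a median of -0.40 over 32 genes (2 lower adjusted over the list alone, adjusted p = 1.56e-12, and adjusted p = 0.0918 with an estimated correlation). Cholesterol synthesis had a median of -0.38 over 25 genes (1 lower adjusted over the list alone, adjusted p = 8.79e-10, and adjusted p = 0.113 with an estimated correlation). Fatty acid synthesis stood at -0.37 (2 of 30 lower adjusted over the list alone, adjusted p = 1.65e-06, and adjusted p = 0.192 with an estimated correlation). PPARα targets stood at -0.25 (adjusted p = 1.55e-08, and adjusted p = 0.113 with an estimated correlation). Periportal genes stood at -0.35 (4 of 21 lower adjusted over the list alone, adjusted p = 2.83e-07, and adjusted p = 0.113 with an estimated correlation). Gluconeogenesis stood at -0.27 (2 of 22 lower adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.113 with an estimated correlation). Hepatocyte markers had all 20 genes below 0 and a median of -0.25 (adjusted p = 2.3e-06, and adjusted p = 0.113 with an estimated correlation). Endothelial markers had all 22 below 0 and a median of -0.24 (adjusted p = 0.000154, and adjusted p = 0.284 with an estimated correlation). No member of these 8 lists passed over all genes tested. In the order given, their medians on day 1 were -0.40, -0.30, -0.46, -0.24, -0.63, -0.29, -0.22 and -0.22, and on day 2 they were -0.31, -0.53, -0.23, -0.36, -0.27, -0.42, -0.45 and -0.42.

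Smaller shifts were found in further lists. Complement and coagulation genes had a median of -0.21 (adjusted p = 0.000136, and adjusted p = 0.278 with an estimated correlation). Male-biased genes had -0.22 (adjusted p = 0.000807, and adjusted p = 0.289 with an estimated correlation), and female-biased genes -0.20 (adjusted p = 0.00545, and adjusted p = 0.212 with an estimated correlation). Growth hormone and insulin signalling stood at -0.20 (adjusted p = 0.00617, and adjusted p = 0.113 with an estimated correlation). Bile acid synthesis and transport stood at -0.17 (adjusted p = 0.00617, and adjusted p = 0.205 with an estimated correlation). Pericentral genes stood at -0.13 (adjusted p = 0.0109, and adjusted p = 0.289 with an estimated correlation), and steroid receptor chaperones at -0.12 (adjusted p = 0.017, and adjusted p = 0.166 with an estimated correlation). In this order the medians of these 7 lists were -0.09, -0.17, -0.30, -0.36, -0.07, -0.23 and -0.13 on day 1, and -0.29, -0.36, -0.06, -0.18, -0.24, 0.01 and -0.19 on day 2. None of their genes passed over all genes tested. Adjusted over the list alone, 2 female-biased genes were lower, 1 signalling gene was higher and 0 passed in the other lists. Oxidative phosphorylation (-0.12, adjusted p = 0.000366, adjusted p = 0.503 with an estimated correlation) differed by 0.11 on day 1 and by -0.61 on day 2. Ribosomal proteins (-0.07, adjusted p = 0.04, adjusted p = 0.79 with an estimated correlation) differed by 0.32 and -0.82. The directions of these last lists, and of pericentral genes, did not hold within both days.

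Targets of the glucocorticoid receptor itself gave few calls. In the list of 32 glucocorticoid-induced genes, 1 was higher and 0 lower over all genes tested, against 1 higher and 3 lower adjusted over the list alone, with a median of -0.24 (adjusted p = 0.000199, and adjusted p = 0.226 with an estimated correlation). This median was -0.05 on day 1 and -1.12 on day 2, and the day 2 value compares AAV-hGRβ replicate 1 with AAV-GFP replicate 3, the array on which 17 of the 32 genes were highest. The member that passed was Cdkn1a, which is also a p53 target. Tat, a tyrosine aminotransferase induced by glucocorticoids, differed by -1.10 (adjusted p = 0.133), and the gluconeogenic enzymes Pck1 and G6pc by -0.70 (adjusted p = 0.42) and -0.77 (adjusted p = 0.278). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, differed by -0.79 (adjusted p = 0.583), by -0.04 on day 1 and by -2.30 on day 2. Fkbp5, a cochaperone of the receptor, differed by -0.12 (adjusted p = 0.976), and its probes disagreed in sign, from -0.12 to 0.83. The clock gene Per1 differed by -0.78 (adjusted p = 0.771), the coactivator Ppargc1a by -0.65 (adjusted p = 0.335) and Igfbp1, a secreted binder of insulin-like growth factors, by -0.19 (adjusted p = 0.948). Nr3c1, the mouse glucocorticoid receptor, stood at 2.31 ± 0.14 with AAV-hGRβ and 2.43 ± 0.12 with AAV-GFP (log2 difference -0.13, adjusted p = 0.847), and its direction turned under normexp correction (0.39), though not with bright local backgrounds replaced (-0.13). Its 4 probes are for the mouse gene, and expression of the delivered human sequence and of GFP was not analysed here.

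**Figure D1:**
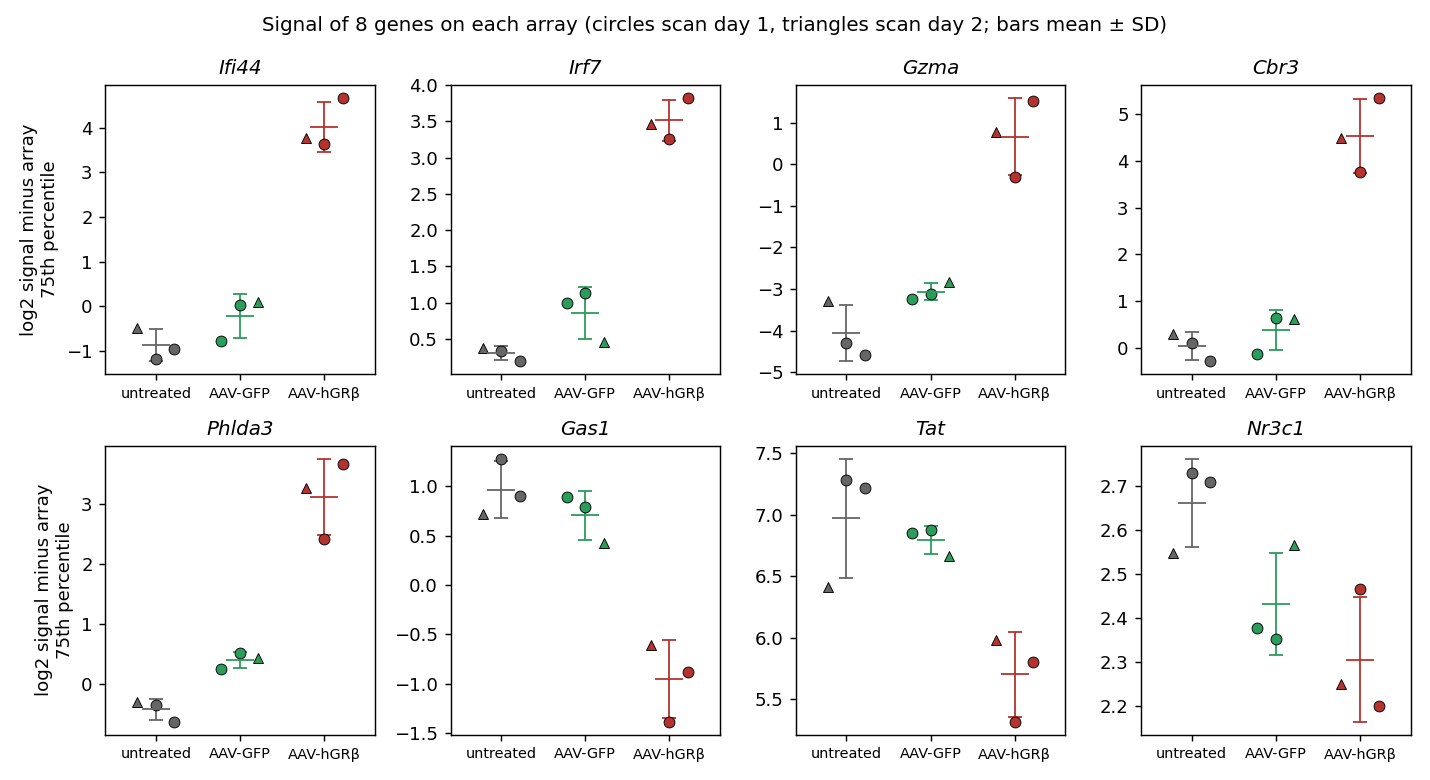
Log2 signal minus the array's 75th percentile (vertical axis) of 8 genes on each of the 9 arrays by group, with circles for scan day 1, triangles for scan day 2 and bars for mean ± SD. The AAV-hGRβ arrays lie above all others for Ifi44 (mean 4.02) and Irf7 (3.51), while Nr3c1 lies between 2.31 and 2.66 in the group means and differs by 0.39 in the opposite direction under normexp correction, though by -0.13 with bright local backgrounds replaced.

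In all, 152 genes changed between AAV-hGRβ and AAV-GFP (139 higher, 13 lower, limma), and 1967 had an unadjusted p under 0.05. All 152 had groups that did not overlap, as did 2651 of all genes tested (15.8%, where chance gives 10%). With scan day as a block 254 genes passed (237 higher, 17 lower), and with slide as a random block 73 (70 higher, 3 lower). With slide as a fixed block, which leaves 3 residual degrees of freedom, 0 passed. The difference in that fixed-block fit rests on AAV-hGRβ replicate 1 and AAV-GFP replicate 3 alone, the arrays of the slide that holds both groups. Its count therefore does not show that slide accounts for the calls. Arrays scaled to their medians gave 101 genes (82 higher, 19 lower). Under normexp correction 13 genes passed, and Ifnb1 (-0.19), Slfn4 (-0.18), Wfikkn2 (-0.28), Oas1b (-0.75), Tnf (-0.69), Bub1b (-0.66) and Ccnb1 (-0.0524) lay below 0. With bright local backgrounds replaced, 159 genes passed and none of these 7 changed sign. The count was 34 without AAV-GFP replicate 1, 101 without AAV-GFP replicate 2, 47 without AAV-hGRβ replicate 1, 47 without AAV-hGRβ replicate 3, 97 without untreated replicate 3 and 98 without untreated replicate 4. Of 44 lists, 30 changed (12 higher, 18 lower), and 2 of these held with an estimated correlation, those of interferon-stimulated genes and of nucleic acid sensors. Lists that did not pass included extracellular matrix genes (median -0.01, adjusted p = 0.945), the acute phase response (0.01, adjusted p = 0.506), stellate cell and fibroblast markers (-0.09, adjusted p = 0.0594) and skeletal muscle markers (-1.22, adjusted p = 0.0653). The muscle value came from AAV-GFP replicate 1, at 4.16, against -0.88 and -0.34 on the other AAV-GFP arrays. It was -2.15 on day 1 and 0.55 on day 2.

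**Figure D2:**
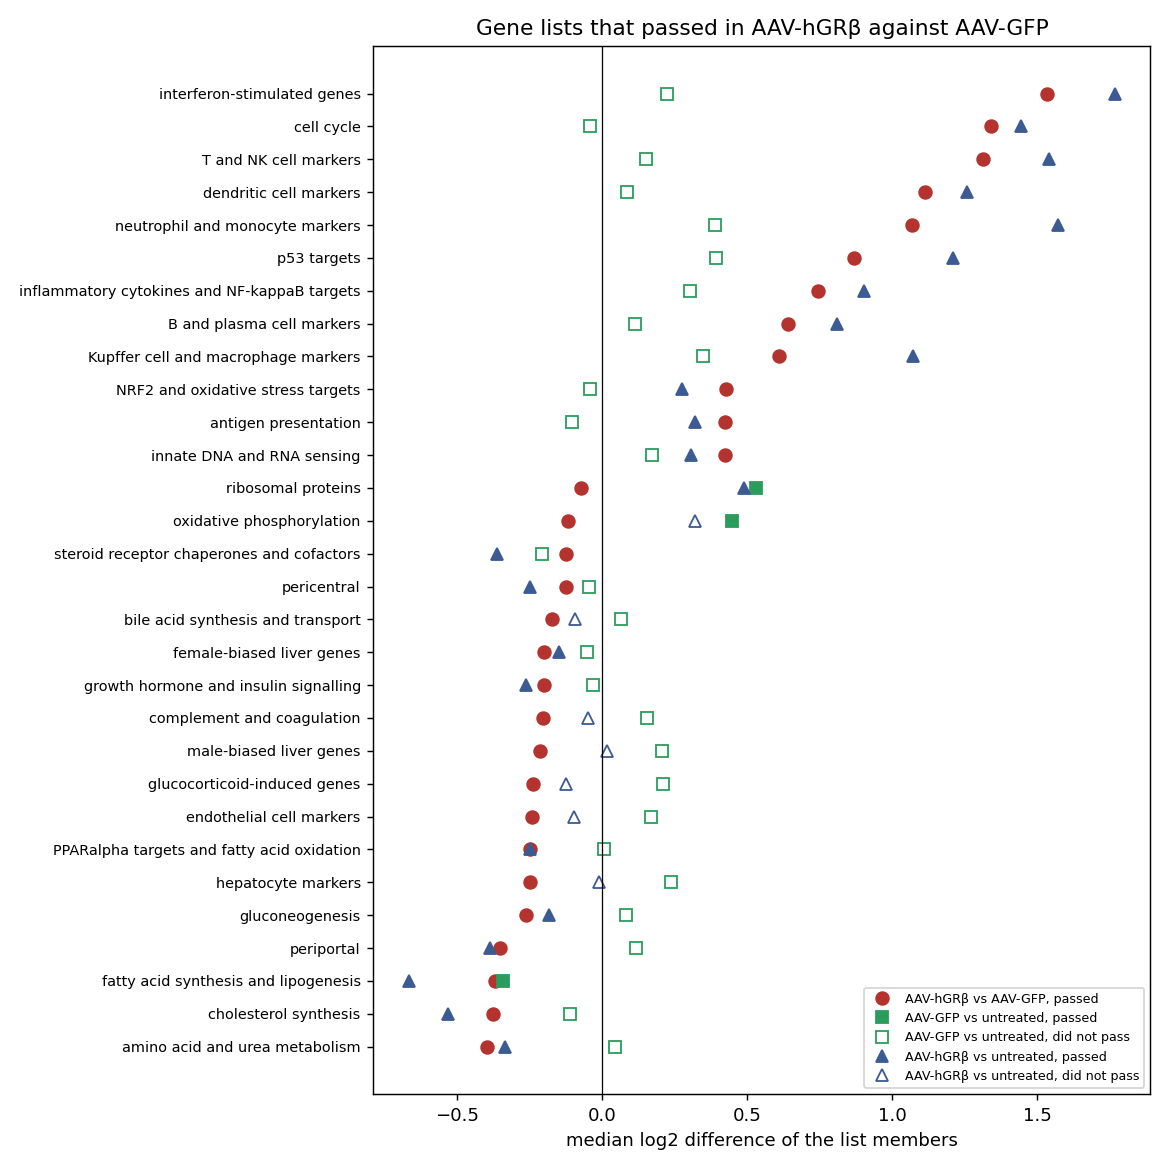
Median log2 difference (horizontal axis) of the 30 gene lists that changed between AAV-hGRβ and AAV-GFP, shown for all 3 comparisons, with filled symbols for lists that passed camera at the preset correlation. The interferon-stimulated list reaches 1.53 against AAV-GFP and 1.77 against untreated, and 0.22 between AAV-GFP and untreated, while 16 of the 18 lists below 0 turned direction under normexp correction, 0 with bright local backgrounds replaced, and the ribosomal list also under quantile normalization and without AAV-GFP replicate 3.

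The vector control was compared with untreated liver to ask what the virus and GFP alone changed. No gene passed: limma called 0 of 16801 genes, the smallest adjusted p was 0.261, and 1639 genes had an unadjusted p under 0.05. The gene with that smallest p was Adam12, a membrane metalloprotease, at -2.51 ± 1.09 in untreated liver and not well above background on any AAV-GFP array, at least 4.91-fold lower. It alone passed with scan day as a block (adjusted p = 0.0264). The next smallest p belonged to Olfr658, an olfactory receptor gene at least 2.38-fold lower (adjusted p = 0.3), and LOC673334, which differed by 1.53 (adjusted p = 0.3), and none of these passed. Kbtbd11 (-1.20) and Tox (-0.97), a thymocyte selection factor, had an adjusted p of 0.491. Fgf14 had the same adjusted p on a probe not well above background on any AAV-GFP array, while another probe, taken without the filter on dim probes, gave 0.22. So had TC1476642 (1.33), NAP029777-1 (1.25), TC1446314 (at least 1.49-fold lower) and A_51_P281078 (at least 2.58-fold higher), which are named only by identifiers.

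Among gene lists, ribosomal proteins were higher with AAV-GFP than in untreated liver, with all 50 genes above 0 and a median of 0.53 (camera adjusted p = 5.94e-08, and adjusted p = 0.949 with an estimated correlation). Oxidative phosphorylation followed with a median of 0.45 over 43 genes (adjusted p = 1.51e-05, and adjusted p = 0.949 with an estimated correlation), and fatty acid synthesis was lower with a median of -0.34 over 30 genes (adjusted p = 0.00105, and adjusted p = 0.949 with an estimated correlation). The fatty acid list did not pass without AAV-GFP replicate 3, without untreated replicate 3 or on scan day 1 alone. In each of these 3 lists 0 genes passed over all genes tested and 0 adjusted over the list alone. Their medians on day 1 were 0.58, 0.52 and -0.23 and on day 2 they were 0.44, 0.24 and -0.33. Interferon-stimulated genes had a median of 0.22 and did not pass (adjusted p = 0.0757), nor did T and NK cell markers (0.15, adjusted p = 0.743) or glucocorticoid-induced genes (0.21, adjusted p = 0.334). Skeletal muscle markers had a median of 1.89 without passing (adjusted p = 0.116), and the value came from AAV-GFP replicate 1, at 4.16, against -0.88 and -0.34 on the other AAV-GFP arrays. Adipocyte markers gave 3 higher and 3 lower genes of 10 adjusted over the list alone and 0 over all genes tested. Of the genes of interest, Tsc22d3 differed by 1.32 (adjusted p = 0.491), Igfbp1 by 0.57 (adjusted p = 0.631), and Pck1 by 0.50 (adjusted p = 0.5). Fkbp5 differed by 0.44 (adjusted p = 0.813), Per1 by 0.20 (adjusted p = 0.905) and Ppargc1a by 0.04 (adjusted p = 0.941). Tat differed by -0.18 (adjusted p = 0.768) and G6pc by -0.32 (adjusted p = 0.576). Nr3c1 differed by -0.23 (adjusted p = 0.526). In this comparison 2479 genes (14.8%, where chance gives 10%) had groups that did not overlap. Without untreated replicate 4, 1 gene passed, and 4 passed when arrays were scaled to their medians.

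Interferon and immune genes also rose in AAV-hGRβ compared with untreated liver. Ifi44 rose from -0.87 ± 0.35 to 4.02 ± 0.56, by 4.89 (adjusted p = 0.000822), or by 2.34 on its other probe. Oas1a rose by 3.91, Irf7 by 3.21 and Zbp1 by 2.67. Interferon-stimulated genes had 30 of 45 higher and 42 adjusted over the list alone. Their median was 1.77, with 1.86 on day 1 and 1.39 on day 2 (adjusted p = 5.38e-30, and adjusted p = 0.158 with an estimated correlation). Gzma rose by 4.71 and Gzmb by 3.26. Cd8a passed (adjusted p = 0.00527) on a probe not well above background on any untreated array, and its other probes gave 2.19 and 2.87. T and NK cell markers had 7 of 28 higher and 1 lower, and 18 and 1 adjusted over the list alone. Their median reached 1.54, with within-day medians of 1.73 and 1.10 (adjusted p = 1.46e-07, and adjusted p = 0.235 with an estimated correlation). Mpeg1 (1.67), the Fc receptor Fcgr1 (1.80), the macrophage apoptosis inhibitor Cd5l (1.26) and the Kupffer cell lectin Clec4f (1.18) were the 4 of 20 Kupffer cell and macrophage markers that rose, against 16 adjusted over the list alone. The median of the list was 1.07, with within-day medians of 1.30 and 0.71 (adjusted p = 6.89e-07, and adjusted p = 0.336 with an estimated correlation). Ly6c1 (3.35) and the chemokine receptor Ccr2 (1.78) were the 2 of 16 neutrophil and monocyte markers that rose, against 11 adjusted over the list alone (median 1.57, adjusted p = 1.52e-05, and adjusted p = 0.312 with an estimated correlation). Dendritic cell markers had 4 of 13 higher and 6 adjusted over the list alone, Ly6d (4.21), Cd83 (2.22), Clec10a (1.60) and Bst2 (1.5). They had a median of 1.26 (adjusted p = 0.00157, and adjusted p = 0.312 with an estimated correlation). The B cell receptor inhibitor Cd22 rose by 1.39, as the member that passed of 13 B and plasma cell markers (median 0.81, 1 adjusted over the list alone, adjusted p = 0.0309, and adjusted p = 0.434 with an estimated correlation), and both this gene (-0.0147) and the list turned direction under normexp correction, though not with bright local backgrounds replaced. The within-day medians of the last 3 lists were 1.89 and 0.96, 1.38 and 0.88, and 0.98 and 0.46. Ifi44, Oas1a, Irf7, Zbp1, Gzma, Mpeg1 and Ly6c1 passed with slide as a random block, and the other genes named in this paragraph did not (adjusted p from 0.0613 for Cd8a to 0.303 for Cd5l).

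Ccl4 (4.11), Ccl5 (2.94), the receptor Tlr2 (2.06) and Tnf (1.58, but -0.48 under normexp correction) were among 9 of 31 inflammatory genes that rose against untreated liver, with 17 adjusted over the list alone. The median was 0.90 over the list (adjusted p = 1.26e-06, and adjusted p = 0.302 with an estimated correlation). Of 24 p53 targets 11 rose, or 16 adjusted over the list alone, with a median of 1.21 (adjusted p = 5.72e-09, and adjusted p = 0.226 with an estimated correlation). Among them were Psrc1 (3.76), Phlda3 (3.53) and Cdkn1a (3.15), and Eda2r was at least 9.32-fold higher. Cell cycle genes had 14 of 38 higher, 24 adjusted over the list alone, and a median of 1.44 (adjusted p = 1.19e-11, and adjusted p = 0.235 with an estimated correlation). They included the ribonucleotide reductase subunit Rrm2 at 2.06, cyclin A2, Ccna2, at 1.82, Prc1 at 1.74 and Ccnb1 at 1.38. NRF2 targets had 5 of 30 higher, with 9 higher and 1 lower adjusted over the list alone, which were Cbr3 (4.48), Gsta2 (2.27), Nqo1 (1.95), Gsta1 (1.81) and Srxn1 (1.41). Their median lay at 0.27 (adjusted p = 0.00157, and adjusted p = 0.336 with an estimated correlation). Nucleic acid sensors had 8 of 19 higher, including Dhx58 (1.90) and Ifi204 (1.80), with 9 higher and 1 lower adjusted over the list alone. The sensors had a median of 0.31 (adjusted p = 0.000342, and adjusted p = 0.158 with an estimated correlation). Psmb9 (1.51) and Psmb8 (1.40), subunits of the immunoproteasome, were the 2 of 19 antigen presentation genes that rose, with 4 adjusted over the list alone and a median of 0.32 (adjusted p = 0.011, and adjusted p = 0.397 with an estimated correlation). Within days, the medians of these 6 lists were 1.03 and 0.64, 1.31 and 1.00, 1.30 and 1.56, 0.37 and 0.33, 0.35 and 0.65, and 0.29 and 0.33. Ly6a rose by 4.16, Slfn4 was at least 5.53-fold and Wfikkn2 at least 4.11-fold higher. Atf3 (2.08), the drug metabolism gene Ugt2b35 (1.23), the collagenase Mmp13 (3.42) and pyruvate kinase, Pkm (0.73), rose although their lists did not pass. Of the genes named in this paragraph Ccl4, Tlr2, Phlda3, Eda2r, Cbr3, Dhx58, Ly6a, Slfn4 and Wfikkn2 passed with slide as a random block, and the others did not, among them all 4 cell cycle genes (adjusted p from 0.0523 for Psrc1 to 0.243 for Pkm). Probes of Ccnb1 ranged from 1.38 to 3.27 and those of Psrc1 from 2.26 to 3.76.

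Genes of lipid synthesis fell in AAV-hGRβ compared with untreated liver. Fatty acid synthase, Fasn, fell from 7.53 ± 0.46 to 6.04 ± 0.08 (adjusted p = 0.0168), the elongase Elovl6 fell by 1.46 and Srebf1, the transcription factor that drives lipid synthesis, fell by 1.20. That list had 3 of 30 lower and 17 adjusted over the list alone. Its median was -0.67, with within-day medians of -0.67 and -0.52 (adjusted p = 7.44e-09, and adjusted p = 0.226 with an estimated correlation). Cholesterol synthesis had 3 of 25 lower and 11 adjusted over the list alone. That median was -0.53, with -0.42 on day 1 and -0.78 on day 2 (adjusted p = 1.28e-08, and adjusted p = 0.226 with an estimated correlation). Among those that fell were the sterol carrier Stard4, which fell by 0.96, and lanosterol synthase, Lss, which fell by 0.98 on 1 probe, while its other probes differed by -0.38 and -0.16. Of 38 PPARα targets 4 fell, or 10 adjusted over the list alone: the fatty acid hydroxylases Cyp4a14 (-1.68), Cyp4a10 (-1.41) and Cyp4a31 (-1.38) and the thiolase Acaa1b (-1.40). The list median of -0.25 turned direction under normexp correction (adjusted p = 1.27e-05, and adjusted p = 0.25 with an estimated correlation). Amino acid and urea metabolism had 2 of 32 lower, Tat (-1.27, adjusted p = 0.0446) and serine dehydratase, Sds (-1.15), and 9 adjusted over the list alone. Its median of -0.34 also turned under normexp (adjusted p = 1.76e-06, and adjusted p = 0.226 with an estimated correlation). Gluconeogenesis had 2 of 22 lower, 6 adjusted over the list alone, and a median of -0.19 that turned under normexp (adjusted p = 0.00248, and adjusted p = 0.235 with an estimated correlation). Periportal genes had 1 of 21 lower, 3 adjusted over the list alone, and a median of -0.39 that turned likewise (adjusted p = 0.000886, and adjusted p = 0.302 with an estimated correlation). Pericentral genes had 0 of 22 lower and a median of -0.25, again turned by normexp (adjusted p = 0.0255, and adjusted p = 0.414 with an estimated correlation). The insulin receptor Insr fell by 1.28 and was the member that passed of 20 growth hormone and insulin signalling genes, with 1 higher and 2 lower adjusted over the list alone (median -0.26, adjusted p = 0.0226, and adjusted p = 0.226 with an estimated correlation). Serpina6, the corticosteroid-binding globulin, fell by 0.90 and was the member that passed of 22 receptor chaperones and cofactors, 1 adjusted over the list alone (median -0.36, adjusted p = 0.00412, and adjusted p = 0.226 with an estimated correlation). Female-biased genes had 3 of 23 lower, among them Tox (-1.19) and the transporter Slc22a26 (-1.24), against 1 higher and 6 lower adjusted over the list alone. The list median was -0.15 (adjusted p = 0.0266, and adjusted p = 0.336 with an estimated correlation). Some of these falls were partly present with AAV-GFP, where the fatty acid list had a median of -0.34 against untreated. Fasn lay at 7.05 to 7.96 in untreated, 6.74 to 7.08 with AAV-GFP and 5.96 to 6.12 with AAV-hGRβ. Insr lay at 1.04 to 2.01 in untreated, 0.62 to 1.11 with AAV-GFP and 0.14 to 0.57 with AAV-hGRβ. For Lss these ranges were 1.45 to 2.01, 0.96 to 1.20 and 0.53 to 0.84. Between AAV-GFP and untreated Tox differed by -0.97, but Tat by -0.18. With slide as a random block none of the falls named in this paragraph passed (adjusted p from 0.0876 for Tox to 0.298 for Cyp4a10), although 10 of the 11 lower lists kept their call. Normexp correction left 0 lower genes, and 341 with bright local backgrounds replaced, where no list turned. From PPARα targets on, the medians of these 8 lists on day 1 were -0.21, -0.33, -0.43, -0.49, -0.36, -0.31, -0.42 and -0.31, and on day 2 -0.37, -0.38, -0.20, -0.27, -0.10, -0.26, -0.11 and -0.18.

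Lists of the clock and of ribosomal proteins passed against untreated liver without holding within both days. Clock genes had a median of -0.58 (0 of 19 passing, adjusted p = 0.00904, and adjusted p = 0.318 with an estimated correlation), with -1.07 on day 1 and 0.02 on day 2. Ribosomal proteins had a median of 0.49 (0 of 50 passing, adjusted p = 0.00591, and adjusted p = 0.731 with an estimated correlation), with 0.89 and -0.39. Adam12 was at least 5.62-fold lower (adjusted p = 0.00781) and Fras1 at least 2.29-fold lower. Gas1 fell by 1.92, Tbc1d16 by 2.02, Odz3 by 1.72, Steap2 by 1.63 and Pgap1 by 1.57, and the lysosomal sulfatase Arsa fell by 1.08. Of these, Adam12 and Fras1 passed with slide as a random block. Glucocorticoid-induced genes had 1 higher and 3 lower of 32, or 1 and 4 adjusted over the list alone, and the list did not pass (median -0.13, adjusted p = 0.105). G6pc differed by -1.08 (adjusted p = 0.0586), Ppargc1a by -0.60 (adjusted p = 0.17), and Per1 by -0.58 (adjusted p = 0.613). Nr3c1 differed by -0.36 (adjusted p = 0.195), Pck1 by -0.19 (adjusted p = 0.694) and Fkbp5 by 0.32 (adjusted p = 0.823). Igfbp1 differed by 0.38 (adjusted p = 0.665) and Tsc22d3 by 0.52 (adjusted p = 0.476), and none of these passed. Hepatocyte markers had a median of -0.01 (adjusted p = 0.0625) and endothelial markers of -0.10 (adjusted p = 0.116).

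Over all genes, 545 changed between AAV-hGRβ and untreated liver (419 higher, 126 lower, limma), and 4292 had an unadjusted p under 0.05. All 545 had groups that did not overlap, as did 4925 of all genes tested (29.3%, where chance gives 10%). With scan day as a block 1214 genes passed (948 higher, 266 lower), with slide as a random block 59 (55 higher, 4 lower), under normexp correction 45, or 881 with bright local backgrounds replaced, and the trend and robust settings gave 1030. Arrays scaled to their medians gave 332 higher and 253 lower genes. The count was 94 without untreated replicate 4, 109 without untreated replicate 3, 1947 without untreated replicate 2, 240 without AAV-GFP replicate 2, 319 without AAV-hGRβ replicate 1, 274 without AAV-hGRβ replicate 2 and 100 without AAV-hGRβ replicate 3. Of 44 lists 24 changed (13 higher, 11 lower), 0 of them with an estimated correlation, where the smallest adjusted p was 0.158, while fry called 20.

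**Figure D3:**
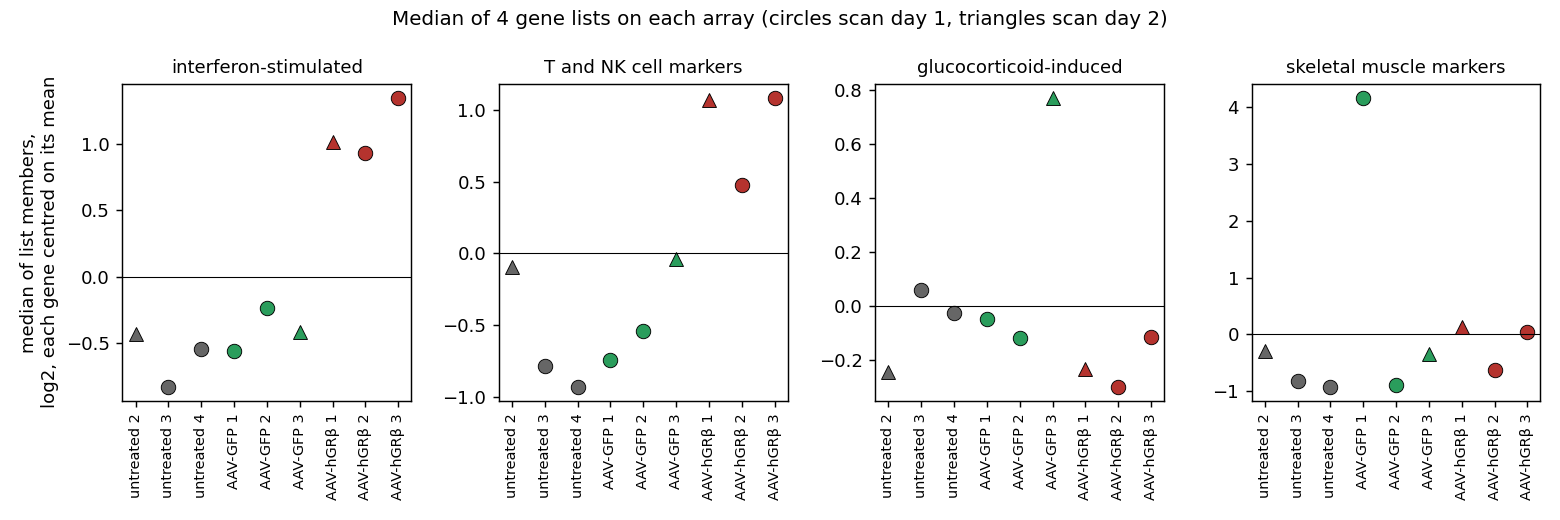
Median over the genes of 4 lists on each array (vertical axis, log2 signal with each gene centred on its mean over the 9 arrays), by group and scan day. Interferon-stimulated genes lie between 0.93 and 1.35 on AAV-hGRβ arrays and between -0.83 and -0.24 on the others, and skeletal muscle markers stand at 4.16 on AAV-GFP replicate 1.

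Genes that differed from both controls were also counted, since AAV-GFP livers had received a vector and untreated livers had not. Ifi44, Irf7, Oas1a, Cbr3, Phlda3, Cdkn1a, Gzma, Cd8a and Ly6a rose and Gas1 and Fras1 fell in both comparisons. In total 137 genes passed against both (129 higher, 8 lower), where independent lists of these sizes would share 3.47 higher and 0.0975 lower genes. In 20 simulations of unchanged groups, with all arrays drawn independently, 0 were shared. The simulations leave out real effects and any correlation within slides or scan days, and the independent lists leave out the shared AAV-hGRβ arrays. So part of the excess can come from slide, and over the independent lists from the AAV-hGRβ arrays, which with 3 were too few to split. A scan day shift common to all groups cancels where all arrays have a value, since each group holds the same number of arrays from each day. With scan day as a block 222 genes passed against both. A day shift that differs between groups would not cancel. Log2 differences of the 2 comparisons correlated at 0.732 across genes, which are not independent replicates, against 0.502 in the simulations, with a covariance of 0.254 against 0.0739 (difference 0.180). The count was 46 with slide as a random block, 33 without AAV-GFP replicate 1, 46 without AAV-hGRβ replicate 1, 44 without AAV-hGRβ replicate 3, 78 without untreated replicate 3 and 70 without untreated replicate 4. AAV-GFP and AAV-hGRβ, each against untreated, shared 0 called genes by limma, since AAV-GFP had none (1639 genes at an unadjusted p under 0.05). Their log2 differences correlated at 0.641 across genes against 0.497 in simulations of unchanged groups, with a covariance of 0.198 against 0.0730 (difference 0.125). The simulated values already hold the shared untreated arrays, but no correlation within slides, which can add to this excess. A scan day shift common to all groups cancels here as well.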

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

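The alternatives that used the arrays of scan day 1 alone, the normexp correction with bright local backgrounds replaced, and the scan day block for gene lists, the overlap and Nr3c1 were chosen only after the data had been seen. The deposited series table and the 1.5-fold minimum gave the same counts of genes as the main setting, and the cause was not tested for the changes below unless stated. Interferon-stimulated and cell cycle genes stayed higher against AAV-GFP and passed under all settings with the preset correlation. Weak signal over background limits dim genes. Without the filter on dim probes 27654 genes were tested, and 29 passed against AAV-GFP, 84 against untreated and 28 against both controls, with 8 lists for AAV-GFP against untreated. The 152 genes called against AAV-GFP in the main setting had all passed that filter, and 29 of them were kept, so the lower count is not a loss of dim genes alone. Scaling to medians moved the median difference of all genes to -0.33 against AAV-GFP and -0.25 for AAV-hGRβ against untreated, from 0.03 and 0.10.

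Under normexp, 13 genes and 18 lists passed for AAV-hGRβ against AAV-GFP, 45 genes against untreated, 13 against both controls and 14 lists for AAV-GFP against untreated, and 12 of the 152 and 37 of the 545 genes were kept. The 5th percentile of corrected signal ran from 61.0 to 1154 across arrays, and from 61.0 to 70.6 once at most 25 bright local backgrounds per array were replaced, so those few spots account for the spread. With them replaced, 159 genes passed against AAV-GFP, 881 against untreated and 153 against both controls, with 30 lists against AAV-GFP and 5 lists for AAV-GFP against untreated. Quantile normalization gave 1 gene and 5 lists for AAV-GFP against untreated and an overlap of 1, and scaling to medians gave 4 genes, 8 lists and an overlap of 2, with 101 genes against AAV-GFP and 90 against both controls. The share of higher genes fell to 81.2% from 91.4% against AAV-GFP and to 56.8% from 76.9% against untreated (332 higher, 253 lower) when scaled to medians, and normexp raised both shares to 100%.

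With slide as a random block 73, 59 and 46 genes passed against AAV-GFP, untreated and both controls. As a fixed block, which leaves 3 residual degrees of freedom, it gave 0 genes against AAV-GFP in limma, with 1940 at an unadjusted p under 0.05. In that fixed-block fit the difference rests on AAV-hGRβ replicate 1 and AAV-GFP replicate 3 alone, so its count does not decide whether slide accounts for the calls. The scan day block gave 254, 1214 and 222 genes, 1 for AAV-GFP against untreated and an overlap of 1. Day 1 alone gave 3 genes against AAV-GFP, 4756 against untreated, 2 against both and 1 for AAV-GFP against untreated. Fits of only the groups compared gave 75 and 343 genes, and trend and robust settings 1030 against untreated. An estimated correlation left 2, 0 and 0 lists for AAV-hGRβ against AAV-GFP, AAV-GFP against untreated and AAV-hGRβ against untreated, and fry 15 and 0 for the former pair.

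No pairing of the samples by replicate number was seen: deviations of same-numbered arrays correlated at -0.32 to 0.24 over 7 pairs, and 1 pair was above 0.1. This cannot exclude a pairing, since most of these pairs lie on different scan days. Across days, the 12 pairs of different groups reached 0.0625 at most. With replicate number as a block 2 genes passed against AAV-GFP, 1 against untreated and 1 against both, with 7 lists for AAV-GFP against untreated.

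Leaving out each array gave 34 (AAV-GFP replicate 1) to 166 (AAV-GFP replicate 3) genes against AAV-GFP, 94 (untreated replicate 4) to 1947 (untreated replicate 2) against untreated, 33 to 129 against both and 0 to 1 for AAV-GFP against untreated and for the overlap. Lists ranged from 28 to 32, from 22 to 25 and, for AAV-GFP against untreated, from 3 to 9 (without AAV-GFP replicate 2), with 6 without AAV-GFP replicate 1, AAV-hGRβ replicate 3 or untreated replicate 4 and 7 without AAV-GFP replicate 3. Nr3c1 against AAV-GFP stayed between -0.21 and -0.06, and a group left with fewer arrays is assumed to vary like the others.

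Some genes changed sign. Under normexp, against AAV-GFP, they were Nr3c1 (0.39), Igfbp1 (0.58), Pck1 (0.0862), Bub1b (-0.66), Ccnb1 (-0.0524), Ifnb1 (-0.19), Oas1b (-0.75), Slfn4 (-0.18), Tnf (-0.69) and Wfikkn2 (-0.28). For AAV-GFP against untreated they were Olfr658 (0.0113), TC1446314 (0.10), Per1 (-0.25) and Ppargc1a (-0.0658), and for AAV-hGRβ against untreated Cd22 (-0.0147), Fkbp5 (-0.42), Nr3c1 (0.0151), Pck1 (0.27) and Tnf (-0.48). With bright backgrounds replaced, Fkbp5 was 0.27 against AAV-GFP and -0.14 for AAV-GFP against untreated, and under median scaling -0.0328 for AAV-hGRβ against untreated. Without the dim filter Wfikkn2 was -0.0236 against AAV-GFP and Fgf14 0.22 for AAV-GFP against untreated. Each of these values is from another probe, which the filter had removed, so the first probe itself did not change sign. The mean of the probes gave Fkbp5 0.40 against AAV-GFP, and -0.11 for AAV-GFP against untreated with Ppargc1a at -0.22.

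Left-out arrays turned genes that had not passed. Against AAV-GFP, Fkbp5 ranged from -0.92 (without AAV-GFP replicate 2) to 1.02 (without AAV-GFP replicate 3), and was also above 0 without AAV-hGRβ replicate 2 (0.0455) or 3 (0.0964), and Igfbp1 ranged from -0.51 to 0.46 (without AAV-GFP replicate 3). For AAV-GFP against untreated, the ranges were -0.69 to 1.24 for Fkbp5 and -0.0797 to 0.94 for Igfbp1, both lowest without AAV-GFP replicate 3. They were -0.66 (without untreated replicate 2) to 0.88 for Per1, also below 0 without AAV-GFP replicate 3 (-0.19), and -0.10 (without AAV-GFP replicate 3) to 0.19 for Ppargc1a, also below 0 without untreated replicate 2 (-0.0663). For AAV-hGRβ against untreated, Fkbp5 ranged from -0.0648 (without AAV-hGRβ replicate 1) to 0.54 and Per1 from -1.44 to 0.10 (without untreated replicate 3). On day 1 alone Fkbp5 was 0.63 and Igfbp1 0.53 against AAV-GFP, and Fkbp5 -0.55, Igfbp1 -0.0785, Pck1 -0.0446, Per1 -1.04 and Ppargc1a -0.21 for AAV-GFP against untreated. Of 1161 values of 47 named genes that passed against AAV-GFP, 683 kept direction and call, 470 lost the call and 8 changed sign. Against untreated these were 1168, 472 and 2 of 1642 values of 69 genes.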

Other observations

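Tests of scan day, slide, cell shares and muscle tissue and the regroupings balanced over scan days below were chosen only after the result was seen, while the counts over other splits and the test of scaling were set beforehand. Transcripts of skeletal muscle stood out on a single array, AAV-GFP replicate 1. Tnnc2 (fast troponin C) was 8.44 above the mean of the other 8 arrays on the log2 scale, Acta1 (skeletal actin) 7.92 and Tnni2 (fast troponin I) 7.54, and the 9 muscle markers tested had a median of 4.16 there against -0.92 to 0.12 on the other arrays. These genes were named after their values were seen. Glucocorticoid-induced genes had a median of 0.77 on AAV-GFP replicate 3 and of -0.30 to 0.06 on the other arrays, with 17 of 32 highest there.

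Many genes differed between scan days, 533 of 16801 in limma with group in the model (428 higher and 105 lower on day 2), and since the days lie on separate slides, day and slide were not separated here. The first principal component held 45.8% of the variance and the next 13.7%. Arrays on a slide shared a correlation of 0.462, and 0.0954 once scan day was a block.

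The rise of interferon-stimulated genes with AAV-hGRβ was set against technical causes. Scan day is argued against by a median difference of 1.57 on day 1 and 1.5 on day 2, where each group has a single array. The same pair of arrays gives the slide value that follows, so that value is not separate evidence from day 2. Slide is argued against by the slide that holds both AAV-GFP replicate 3 and AAV-hGRβ replicate 1, where the median difference was 1.5 with 43 of 45 genes higher, against a largest shift between slides within a group of 0.20, and 17 of 24 genes kept the call with slide as a random block. A larger share of T and NK cells stays open, since their markers had a median difference of 1.31, and of these 28 markers 1 is in another list and 18 were well above background on all untreated arrays. A response to the transgene is a hypothesis that may hold beside such cells, and vector dose or purity, which the labels do not give, cannot be told apart from it here.

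Lower metabolic lists with AAV-hGRβ against AAV-GFP may come from a lower share of hepatocytes, from scaling, or from added immune cell RNA. A lower hepatocyte share that raises all other cell types alike is argued against by T and NK cell markers. These exceeded endothelial markers by 1.67 on the log2 scale (SE 0.229 across marker genes). That SE treats the genes as independent and leaves out the spread between arrays. A lower share through added immune cells stays open, since it could lower endothelial markers as well (median -0.24). It cannot be told apart here from added immune cell RNA. Scaling stays open, since 11 of the 18 lower lists kept call and direction after quantile normalization. Immune cell RNA beside unchanged hepatocytes also stays open against AAV-GFP. There hepatocyte markers had a median difference of -0.25. The genes of 6 metabolic lists (amino acids, cholesterol, fatty acids, PPARα, periportal, gluconeogenesis) differed from these markers by -0.0157 (SE 0.123, from the spread between arrays) on average, without the genes that both hold. Of the 20 markers, 8 are in another list. Their median difference was 0.24 for AAV-GFP against untreated and -0.01 for AAV-hGRβ against untreated. So the -0.25 came with higher values in AAV-GFP than in untreated liver. T and NK cell markers had a median of 1.54 for AAV-hGRβ against untreated, where added immune cell RNA would lower hepatocyte markers too. Against untreated the 6 lists differed from the hepatocyte markers by -0.29 (SE 0.123). Immune cell RNA alone would lower both alike, so this gap argues against it, though weakly. The SE takes arrays as independent, while arrays on a slide shared a correlation of 0.462. As single lists, periportal genes (-0.22, SE 0.179) and gluconeogenesis (-0.21, SE 0.165) differed less clearly. Since the gap was -0.0157 against AAV-GFP, it lay mostly between AAV-GFP and untreated. It therefore does not decide what lowered the lists with AAV-hGRβ. An effect of the transgene on hepatocytes is a further hypothesis that was not tested separately.

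For the muscle transcripts in AAV-GFP replicate 1, muscle tissue taken with the liver is a candidate source. A test asking for all 9 markers to be highest there left it undecided, with 8 of 9, as Myh1 was -0.30 from the mean of the others. A further test, chosen after that outcome with genes listed before their values were seen, took 19 other muscle transcripts. Over all 19 the median difference was 1.39, which the hypothesis needs. Of them 13 were highest there, among them Cox6a2 (6.00), Cox8b (5.98), Tcap (5.96) and Pgam2 (5.22). Of the 9 markers, 1 is in another list and 6 were well above background on all untreated arrays. Slide or scan day is argued against by AAV-GFP replicate 2, from the same slide and day, where the median difference was -0.33; no biological explanation was tested.

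Other splits of the arrays were fitted for each comparison, and 10 splits are too few for a share under 0.05. Against AAV-GFP, 1 of 10 splits, the real one, reached 152 genes, and the highest other count was 0. It was also 1 of 10 for lists, with 30 and at most 28. For AAV-GFP against untreated, 10 of 10 splits gave as many genes (0, and at most 0 in the others), which a real count of 0 fixes in advance. It was also 10 of 10 for lists (3, and at most 16). For AAV-hGRβ against untreated 1 of 10 splits reached 545 genes, with at most 3 in the others, and 1 of 10 reached 24 lists, with at most 21. Over 100 regroupings of the 9 arrays, 1 gave as many genes against both controls as the real 137, the highest other being 1. Over 100 regroupings that kept the groups balanced over scan days it was also 1, the highest other being 129. In 2 of these others the AAV-hGRβ arrays stayed together, and where they were parted the highest count was 0. High counts thus came only where the AAV-hGRβ arrays stayed together. Chance is not excluded for that count, since the regroupings treat all arrays as alike while arrays on a slide shared a correlation of 0.462. Slides, most of which held a single group, were not balanced in these regroupings. The overlap of AAV-GFP and AAV-hGRβ each against untreated was 0, so as many or more in 100 of 100 regroupings was fixed in advance and decides nothing. The highest, 137, equals the real count against both controls, as labelling the AAV-hGRβ arrays as untreated would give.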
